A study of Mus musculus with 12 samples.

How the data were processed

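Total RNA of hand-picked pancreatic islets of male C57BL/6 offspring, 2 to 3 months old, was measured by TaqMan RT-PCR with a FAM probe, per the labels' protocols, in 6 LP0.5 and 6 Control samples. Per the submitters' processing notes limma was used, with its version and role not given in the sources used here. The reference used for normalization, the detection limit and the way samples were averaged are likewise not given in the sources used here.

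The authors deposited 1 table of linear ratios (fold values), headed as low-protein against control, per the file headers, with 1 value for each of 846 spots and 190 spots without a value. A second deposited table pairs each spot with an assay number and a small RNA name and holds 12 columns of per-sample values. The names of those 12 columns match no sample label, so they were given no group and not used here. The planned limma tests per miRNA, camera and fry list tests, counts of detected miRNAs and tests of controls need per-sample values and were not run; everything below comes from the ratios in the authors' deposited table, for which no genome build is named. Threshold cycles behind the ratios were not analysed here, since unmatched columns were used in no step. Without replicate values the error of a ratio cannot be given, so spread was described from repeated control spots and from pairs of different assays of 1 miRNA name.

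Spots were split into an A set and a B set of assays, 8 blocks each, by the spot code. Within each set the mean log2 ratio of the 8 U6 spots was 0, a finding from the values, so the ratios are relative to U6 and a change of U6 itself would shift every ratio of a set. Ratios were converted to log2, and spots of 1 miRNA name were averaged on that scale. The 13 lists of miRNAs and the rule for named miRNAs were fixed before the data were examined. Panel names were matched to list names without species prefix and assay number, and an older or arm-less name was taken for 10 of them (such as 124a for miR-124). Starred strands were not taken as list members, except miR-126-5p, which was fixed as a member and whose assay carries a starred name. The rule named miRNAs by p-value and by abundance, which would need the per-sample columns and were not used here, and in any case miR-375, miR-7a, miR-199a-3p, miR-342-3p, miR-152 and the small RNA controls. The remaining named miRNAs were therefore chosen after their values were seen: list members at least 1.5-fold from 1 or among the nearest to or farthest from 1, well-known list members, ends of the distribution, and hairpins with both strands at least 1.5-fold from 1.

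A list was described by the percentile of its median log2 ratio among 10000 random lists of the same size drawn from the 528 miRNA names with a ratio, and said to stand apart outside the central 95%. Random lists were not matched on abundance, which was not analysed here. Correlations between paired assays and between hairpin strands used Spearman's rho and Pearson's r with 100000 permutations, two-sided. MiRNA genes within 10 kb were taken as neighbours from a mouse gene table of assembly GRCm38.p6, used for gene order only; 328 of 387 hairpin names were matched. A hairpin's level for this test was the mean of its assays without starred strands, under the panel's own names, so strands listed under an older or other name did not enter. Adjusted p-values are Benjamini-Hochberg over 5 relations. The 1.5-fold limit, the split into A and B sets, the pairs of assays, the strands, the neighbours and the percentile statistic were chosen after the data were seen. Alternatives covered the reference, the A or B set, the fold limit, starred strands, extreme ratios and the distance between neighbours.

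The statistics were tested on simulated data, 100 simulations each. A list of 12 among 528 miRNAs stood apart in 75 simulations with a log2 shift of 0.5, in 100 with a shift of 1, and in 6 with none. For a list of 9 these numbers were 46, 97 and 8. A correlation of 0.5 over 38 pairs was found in 87 simulations and with none in 5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.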

Results

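MicroRNA (miRNA) levels were compared in pancreatic islets, the hormone-secreting cell clusters that hold the insulin-producing beta cells, from male C57BL/6 mice aged 2 to 3 months. The mothers had been fed a low-protein diet (LP0.5) or a control diet through pregnancy, and the question was which islet miRNAs differ in the adult offspring after that exposure. The labels list 6 LP0.5 and 6 Control samples. Total RNA was measured by TaqMan real-time PCR on a panel of 846 spots in 16 blocks. Of these spots, 750 assayed miRNAs, 80 assayed 5 small RNA controls and 16 assayed a plant miRNA. The authors' deposited table gives 1 linear ratio per spot, headed as low-protein against control, and lists a ratio for 566 of the 750 miRNA spots, which carry 528 distinct miRNA names. It carries no replicate values and no error, so no ratio below has a replicate check or a p-value, and the amplification cycles behind each ratio were not analysed here.

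The direction of the ratio rests on the column heading alone. By that heading a value above 1 means a higher level in LP0.5 islets. In the authors' deposited table miR-199a-3p was listed at 0.422. The study is known for naming this miRNA among those raised in low-protein islets, which is opposite to the heading. The measure, samples and normalization behind that naming are not given in the sources used here. A different normalization therefore cannot be told apart from a reversed ratio. The listed value also lies inside the 5.98-fold range by which paired assays of 1 miRNA name differed. MiR-342-3p, linked to the study in the same way, was listed at 1.24 in the authors' deposited table, which goes with the heading. MiR-152, a further miRNA linked to the study, was listed at 0.696 in the authors' deposited table, and these values together do not settle the direction. Ratios are therefore given as listed above or below 1.

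Most miRNAs were listed close to 1. The median ratio over the 566 miRNA spots was 1.01, and the middle part of the distribution, from the 25th to the 75th percentile, ran from 0.792 to 1.27. A ratio at least 1.5-fold from 1 was listed for 200 spots (35.3%), 105 of them above 1 and 95 below. With the snoRNA135, snoRNA202, U87 and Y1 controls as the reference in place of U6, the split was 91 above and 130 below, so the share above 1 went from 52.5% to 41.2%; without 1 outlying U87 spot in that reference it was 37.8% (82 above, 135 below). The tails were long. In the authors' deposited table miR-294 was listed at 3.63e+07 and 1 of the pair of miR-673 assays at 3.13e+07, while miR-1199 was listed at 0.000109.

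For scale, the same miRNA name measured by a pair of assays often gave different ratios. Among 38 such pairs the median difference was 1.31-fold, 15 pairs lay more than 1.5-fold apart and 9 lay more than 2-fold apart. The authors' deposited table listed miR-200b at 1.06 and 1.07, miR-200c at 1.13 and 1.11, and miR-223 at 1.18 and 1.24. It listed miR-143 at 0.190 and 1.11, miR-370 at 5.06 and 0.951, and miR-20b at 0.257 and 0.827, each pair again from the authors' deposited table. Across the 38 pairs, which are not independent replicates, Spearman's rho was 0.249 (two-sided permutation test, p = 0.132, adjusted p = 0.506 over a family of 5 relations) and Pearson's r was 0.0481 (p = 0.543, permutation test, adjusted p = 0.933). The Pearson value includes the miR-673 pair, at -0.24 and 24.9 on the log2 scale. It can rest largely on that pair and was not computed without it. The 95th percentile of the difference between paired assays was 5.98-fold, so a single ratio nearer to 1 than that lies inside the range by which paired assays differed. The assays of a pair carry different numbers and in part different species names, so this range can include differences between assays besides measurement error. Repeated spots of 1 control assay lay closer together, with a 95th percentile of 1.37-fold from their own median.

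**Figure D1:**
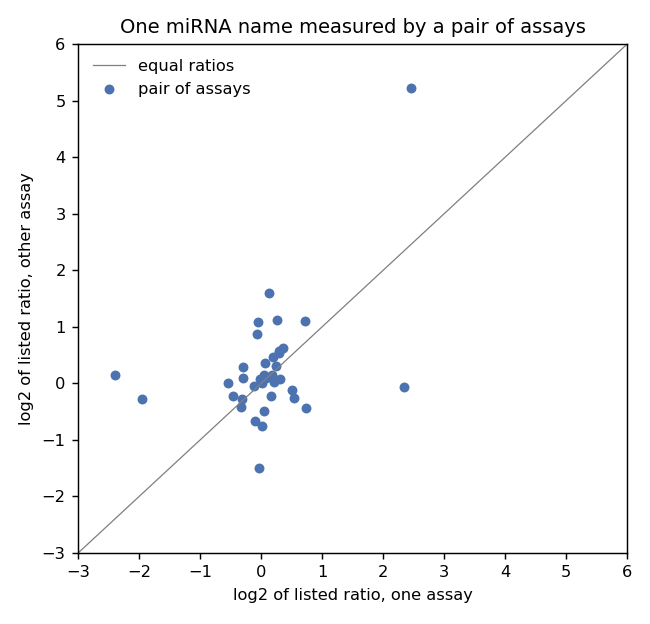
Log2 of the ratio listed by the authors for 1 assay of a miRNA (x axis) against that of a different assay of the same miRNA name (y axis), 1 point per pair, with the line of equal ratios. Of 38 pairs, 37 are drawn and 1 (miR-673, 3.13e+07 for 1 of its assays) lies outside the axes; 15 pairs differ by more than 1.5-fold, and the direction of the ratio rests on the column heading.

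Islet-enriched miRNAs were listed near 1. The median ratio of the 18 miRNAs on this list was 1.09, with 12 above 1 and 6 below, and it lay at percentile 79.8 of 10000 random lists of that size drawn from the panel; with the snoRNA, U87 and Y1 reference the median log2 ratio turned from 0.12 to -0.06, with 6 above 1 and 12 below. In the authors' deposited table miR-375, the most islet-selective miRNA and a regulator of insulin secretion, was listed at 1.17, and miR-7a, a negative regulator of beta cell proliferation, at 0.918. The only member at least 1.5-fold from 1 was miR-7b, listed at 0.523 in the authors' deposited table. The miR-183 family, abundant in sensory and neuroendocrine cells, was listed in the authors' deposited table at 1.45 for miR-183, 1.15 for miR-182 and 0.946 for miR-96. From the miR-200 family, which maintains epithelial identity, the authors' deposited table listed miR-141 at 0.744, miR-429 at 0.782 and miR-200a at 0.822, each below 1, while both assays of miR-200b and of miR-200c were above 1.

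MiRNAs known to act on insulin secretion or beta cell growth were more often listed below 1 than above it. Of 25 members, 17 were below 1 and 8 above, with a median ratio of 0.913 at percentile 12.9 of random lists, inside their central 95%. Members at least 1.5-fold from 1 were miR-9, miR-338-3p and miR-211, listed in the authors' deposited table at 0.558, 0.613 and 0.632. The p53-induced miR-34a was listed at 0.679 and miR-152 at 0.696 in the authors' deposited table. MiR-26a and miR-30d were listed in the authors' deposited table at 0.989 and 1.06.

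The list of miRNAs with Mtor, the kinase at the centre of nutrient sensing, as a known target went both ways. Of 13 members with a ratio, 7 were above 1 and 6 below, and the median ratio of 1.10 lay at percentile 78.3; the median log2 ratio turned from 0.14 to -0.06 with the snoRNA, U87 and Y1 reference, and the mean of log2 ratios held within 2 was -0.02. MiR-193a was listed at 21.7 in the authors' deposited table, and the members at least 1.5-fold below 1 were miR-199a-3p, miR-7b and miR-101b, listed there at 0.422, 0.523 and 0.663. MiR-342-3p was listed in the authors' deposited table at 1.24. MiR-199a-3p, miR-342-3p and miR-152 are linked to this study, so their values are not independent evidence.

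The miR-17-92 cluster and its paralogs, which promote proliferation and cell survival, stood apart from the panel. All 12 members with a ratio were listed below 1, with a median ratio of 0.687 at percentile 0.56 of random lists. Random lists draw miRNAs independently, whereas these members are paralogs and share gene clusters. The 12 values may therefore not be independent, and the percentile can overstate the distance. This was the only one of the 13 lists outside the central 95% of random lists, where 0.65 would be expected by chance if the lists were independent. Its percentile stayed between 0.05 and 0.86 under the other settings run for this list. Most of these settings could change it little. No member is shared with another list, lies beyond 4-fold or is starred, so the settings on these points left the 12 values as they were. A change of reference or division by set medians moved the random lists as well. At least 1.5-fold below 1 were 6 members, among them, in the authors' deposited table, miR-25 at 0.329, miR-363 at 0.411, miR-92a at 0.460 and miR-17 at 0.490. The others were listed in the authors' deposited table from 0.840 for miR-19a to 0.957 for miR-20a, including miR-106a at 0.873 and miR-93 at 0.921.

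The let-7 and miR-98 family, which restrains proliferation and insulin signalling components, was listed mostly above 1 relative to U6, but not relative to the other small RNA controls. Of 9 members, 8 were listed above 1 and 1 below, none at least 1.5-fold from 1, with a median ratio of 1.17 at percentile 88.7; with the snoRNA, U87 and Y1 reference 5 were above 1 and 4 below, and the median log2 ratio went from 0.23 to 0.03. In the authors' deposited table the listed ratios ran from 0.840 for let-7f to 1.35 for miR-98.

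**Figure D2:**
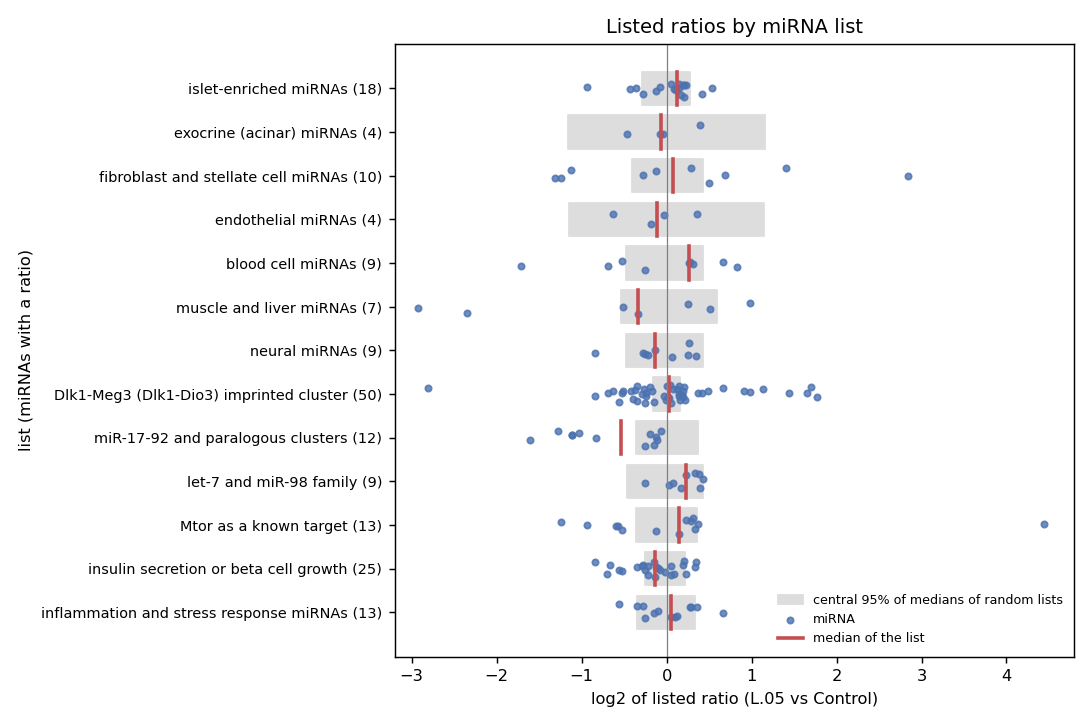
Log2 of the ratio listed by the authors (x axis) for the miRNAs of each of 13 lists (y axis, number with a ratio in brackets), 1 point per miRNA, with the list median as a red line and the central 95% of medians of random lists as a grey band. Only the median of miR-17-92 and its paralogs (ratio 0.687) lies outside its band; miR-673 lies beyond the axis, and the direction of the ratio rests on the column heading.

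MiRNAs of the Dlk1-Meg3 imprinted cluster, a maternally expressed group abundant in beta cells and neurons, were spread around 1. Of 50 members, 27 were above 1 and 23 below, 9 at least 1.5-fold above and 4 at least 1.5-fold below, and the median ratio of 1.02 lay at percentile 58.7; with the snoRNA, U87 and Y1 reference the median log2 ratio turned from 0.03 to -0.14, with 16 above 1 and 34 below. The authors' deposited table listed miR-758 at 3.40, miR-299 at 3.25, miR-667 at 3.16 and miR-665 at 2.71. The miR-299 spot is in the B set, where the plant miRNA assay, which has no mouse target, was itself listed from 2.59 to 3.37. The other strand, miR-299-5p, was listed at 1.37 in the authors' deposited table. At the other end, miR-380-3p was listed at 0.143 and miR-154 at 0.556 in the authors' deposited table.

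Markers of other cells that an islet preparation can hold had list medians inside the central 95% of random lists. This does not show an unchanged cell content, because the band is wide for short lists. For the 4 exocrine miRNAs it ran from -1.16 to 1.16 on the log2 scale. The 4 exocrine miRNAs had a median ratio of 0.958 at percentile 42.2, and the authors' deposited table listed the acinar miR-216a at 0.726 and miR-216b at 0.970, and the assays of miR-217 at 0.950 and 1.83. The 4 endothelial miRNAs had a median of 0.926 at percentile 35.1, and in the authors' deposited table miR-126-3p was listed at 0.975 and miR-126-5p at 0.647. The 10 fibroblast and stellate cell miRNAs had a median of 1.06 at percentile 64.5, with 3 at least 1.5-fold above 1 and 3 below; their median log2 ratio turned from 0.08 to -0.08 with the snoRNA, U87 and Y1 reference and to -0.13 among miRNAs within 4-fold of 1. In this group the authors' deposited table listed miR-199a-3p at 0.422 and miR-199a-5p at 0.403, against miR-199b at 7.14 and miR-145 at 2.66. MiR-10b counted as above the limit only as the mean of a pair of assays, listed there at 1.19 and 2.18. The 9 blood cell miRNAs had a median of 1.20 at percentile 90.7, with 5 above 1 and 4 below; without members shared with other lists the median log2 ratio turned from 0.26 to -0.53 (percentile 5.13), and the mean of log2 ratios held within 2 was -0.09. Among them the authors' deposited table listed the lymphocyte miR-150 at 1.78 and the inflammation-linked miR-155 at 1.59, the red cell miR-451 at 0.620 and miR-142-5p at 0.305, while the other strand, miR-142-3p, was listed at 1.20.

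Muscle, neural and stress-related miRNAs lay inside the central 95% of random lists too. The 7 muscle and liver miRNAs had a median ratio of 0.794 at percentile 8.21; among miRNAs within 4-fold of 1 the median log2 ratio turned from -0.33 to 0.25 (percentile 87.5). The authors' deposited table listed miR-499 at 0.131 and miR-206 at 0.196 but miR-133a at 1.98. The 9 neural miRNAs had a median of 0.913 at percentile 24.3, and their median log2 ratio turned from -0.13 to 0.07 without members shared with other lists. MiR-124 was listed at 1.27 in the authors' deposited table. The 13 inflammation and stress miRNAs had a median of 1.04 at percentile 59.5, with 1 member, miR-155, at least 1.5-fold above 1 and none as far below; their median log2 ratio turned from 0.05 to -0.14 with the snoRNA, U87 and Y1 reference.

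Mature strands paired by hairpin name were not detectably related in ratio. Names were matched without species prefix. Some pairs therefore join assays named for different species (such as miR-196a and miR-493) or a strand numbered by gene copy with an unnumbered one (such as miR-30c). Across 109 hairpin names with both strands listed, Spearman's rho was 0.0211 (two-sided permutation test, p = 0.826, adjusted p = 0.826) and 54 pairs were on the same side of 1. The strands lay in different assay sets for 79 pairs and in the same set for 30. Both strands were at least 1.5-fold from 1 on the same side for miR-10b and miR-770 (above) and miR-196a and miR-199a (below), and on opposite sides for miR-18a, miR-493, miR-503, miR-712 and miR-1941. The main strand of miR-10b passed only as the mean of a pair of assays, listed at 1.19 and 2.18 in the authors' deposited table. Neighbouring miRNA genes within 10 kb, in 28 clusters, were not shown to have ratios closer in rank than random ones, with a mean rank difference of 39.7 against 43.3 for random neighbours (permutation test, p = 0.203, adjusted p = 0.506).

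The small RNA controls differed in how far their repeated spots ranged, least for U6. Each was assayed at 16 spots, and the median ratio was 0.999 for U6, 1.06 for snoRNA202, 1.09 for U87, 1.21 for snoRNA135 and 1.32 for Y1. Their spots ranged from 0.961 to 1.03 for U6, from 0.996 to 1.20 for snoRNA202, from 0.850 to 1.56 for snoRNA135 and from 0.883 to 1.91 for Y1, as listed in the authors' deposited table. U87 ranged from 0.133 to 1.29, the low end coming from 1 spot of the authors' deposited table. Over the 80 control spots the 95th percentile of the deviation from a control's own median was 1.37-fold, and it was 1.41-fold over the 64 spots other than U6. The ratios of the 8 U6 spots of each assay set (A or B) had a mean log2 of 0, so the listed ratios are relative to U6 within each set.

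**Figure D3:**
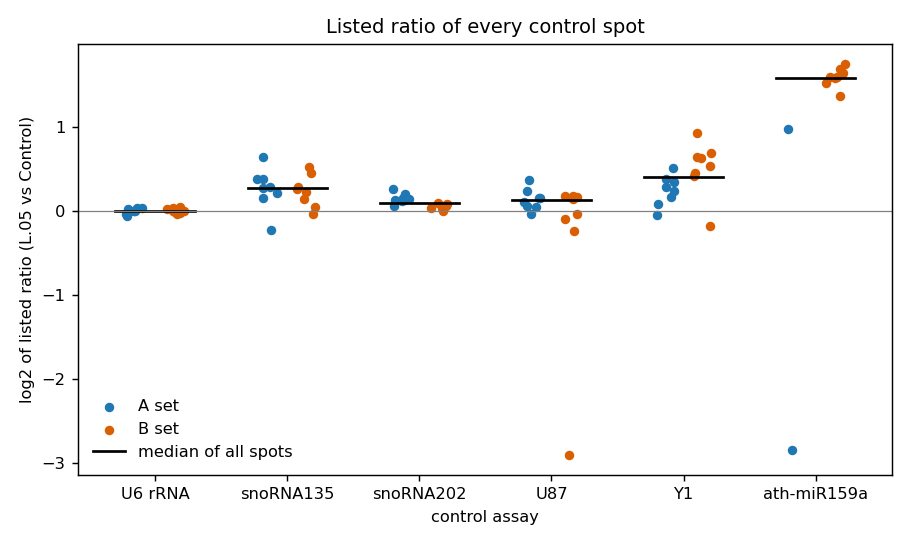
Log2 of the ratio listed by the authors for each spot of 5 small RNA controls and of the plant miRNA assay (x axis), coloured by assay set (A or B), with the median of all spots as a black line. U6 spots lie within 0.961 to 1.03 and the plant assay near 3.01 in the B set; the direction of the ratio rests on the column heading.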

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

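The tests in this part were chosen after the values were seen. A signal appeared outside the main measurement: the plant miRNA ath-miR159a, which mice lack and which the panel carries as a negative control, had a ratio at 10 of its 16 spots. In the B set all 8 spots were listed, from 2.59 to 3.37 with a median ratio of 3.01, while in the A set 2 of 8 were listed, at 0.139 and 1.96 in the authors' deposited table. In the B set the highest median of the 5 small RNA controls was 0.58 on the log2 scale (Y1), against 1.59 for the plant assay. These medians argue against a change of U6 alone as the whole cause. They cannot judge a difference in RNA input, which would move the controls together with U6 but not an assay without a target. Ratios near 3 were thus listed in the B set for an assay that has no mouse target. The level behind these ratios also stays open, as it was not analysed here: a ratio may also be listed for an assay near the end of the reaction. No biological explanation was tested.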

How the results depend on the processing

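All alternatives here except the snoRNA135, snoRNA202, U87 and Y1 reference and the lists without shared members were chosen after seeing the data. Counts of miRNA spots at least 1.5-fold from 1 (105 above, 95 below) changed by more than 1.5 times only where taken from 1 assay set, by construction smaller: 40 above and 48 below in the A set, 65 and 47 in the B set, with 45.5% and 58.0% above 1. They were 70 and 67 at 2-fold. With the snoRNA, U87 and Y1 reference they were 91 and 130, which turns the majority from above 1 to below; that reference moves ratios by 0.20 (A set) and 0.12 (B set) on the log2 scale. The B value rests on 1 outlying U87 spot: without it the shift was 0.22 and the counts 82 and 135. Correlations of repeated assays and of hairpin strands and the neighbour test passed no threshold under any setting run. Exactly 1 list, miR-17-92 and its paralogs, stood apart under every alternative run, though most of these left its member values unchanged or moved the random lists with it. Of the values of 13 lists under other settings, 87 moved by less than the mean SD of control spots and 4 by more. Those 4, on the log2 scale, were those of the fibroblast list (0.39 without shared members), the blood cell list (-0.53 without shared members, and -0.09 as a mean of ratios held within 2) and the muscle and liver list (0.25 within 4-fold). The cause was not tested. The limit includes the outlying U87 spot, which widens it, and is the SD of single spots rather than of list medians. Moves within it are therefore not shown to be small: the islet-enriched median, counted among the 87, turned from 0.12 to -0.06 with the snoRNA, U87 and Y1 reference. The 87 also hold values that could not move. Taking starred strands out of the random lists changed no list median. Lists without shared members, or without members beyond 4-fold, stayed as they were under those settings. No paired analysis was possible because the comparison table holds 1 ratio per spot and the per-sample columns carry no matching replicate number. For the same reason the settings fixed in advance for Ct limits, detection filters, undetermined values, raw or median-scaled Ct, quantile normalization, sample weights, variance models, left-out samples, permutation of samples, estimated correlation and fry were not run. The cycles behind a ratio were not analysed here, so no limit by level is given.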

Other observations

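The tests in this part were chosen after the values were seen. Outside the lists, the authors' deposited table listed the embryonic miRNAs miR-367 at 11.8, miR-302a at 2.63 and miR-302b at 0.106. These were picked after their values were seen, so they are values only.

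The miR-17-92 list lay below 1 in all 12 members. A shift common to all miRNAs of the A or B set was too small to account for it: the set medians were -0.03 (A) and 0.07 (B) on the log2 scale. Division by them could therefore move the list median only slightly, and it was -0.51 (log2) afterwards. Chance stays open: the probability that at least 1 of 13 random lists lies as far out was 0.136, a test set after a first look at the percentile alone. A changed level of the precursors, a hypothesis linking the list to maternal diet, cannot be told apart from other causes, and its direction in LP0.5 islets is not settled. Of 6 starred strands, 1 was below 1 (median ratio 1.14), against a median of 0.871 for their main strands. That gap is smaller than the 0.70 (log2) that random lists of that size allow, a limit set after a first version that used no spread. The starred strands were all in the B set and their main strands all in the A set, so strand and assay set cannot be told apart. The comparison also leaves out miR-25, miR-363, miR-92a and miR-20b, which were among the members at least 1.5-fold below 1.

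Both strands of miR-199a were listed near 0.4 (0.422 and 0.403). A different share of fibroblasts and stellate cells as the whole cause could not be judged. The other 8 list members had a median of 0.39 (log2), which lies 1.67 above the miR-199a strands. That gap exceeds the members' SD of 1.20 and the 0.50 that random lists of that size allow. It lies inside the 2.58 (log2) by which paired assays of 1 miRNA name differed at the 95th percentile. The markers miR-214, miR-143 and miR-145 alone gave a gap of 1.77 against 1.28 and 1.38, though miR-143 itself was below 1, and this test was revised after its values were seen, earlier versions having left the question open or counted members. Chance agreement of unsteady ratios stays open and may suffice, since 4 hairpin names had both strands at least 1.5-fold from 1 on the same side and 5 on opposite sides. Of those 4, miR-10b counted only through the mean of assays listed at 1.19 and 2.18. Maternal diet stays untested, as the direction of the ratio is not settled.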
